A study of Mus musculus with 6 samples.

How the data were processed

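RNA was sequenced from GC-2spd (GC2) cells, a mouse cell line that the labels describe as a spermatocyte line. The 6 libraries fall into 3 groups of 2 by the agent named in the labels, namely control, triptolide and triptonide. The design text of the series speaks of testis, while every sample label names the cell line, so the samples are treated here as cultured cells. Per the labels' protocols, cells were seeded at 100000 per well in 6-well plates with 2 mL of medium and cultured for 12 h before a 24 h exposure to 0.1 µM triptolide. The protocol has the same wording for all samples and gives no dose or time for triptonide, so the doses of the 2 compounds cannot be said to match. Total RNA was depleted of ribosomal RNA with a Ribo-Zero kit and made into strand-specific libraries with a NEBNext Ultra Directional kit, which were read as 150-base paired ends, per the labels' protocols.

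The deposited table holds 1 FPKM value (fragments per kilobase of transcript, relative to the mapped fragments of the library) for each transcript and library, as computed by the authors. STAR and StringTie are the tools named in the submitters' processing notes, without versions. Those notes name the build hg19, a human assembly, whereas the transcript IDs are mouse Ensembl IDs, so the build stays unsettled and no coordinates are given. The table has 65535 transcripts, of which 65189 carry mouse Ensembl transcript IDs. The other 346 carry locus numbers of the kind that transcript assembly tools give, at 253 loci, and are called unannotated transcripts here. A sheet of the older spreadsheet format holds 65535 rows below 1 header line, so the table may be part of a longer one, and its column sums are not library depths. A total of 15228 transcripts were listed at 0 FPKM in all 6 libraries.

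The file does not pair transcripts with genes, and 0 of the 65535 IDs matched the gene name tables used here. The transcript was therefore the unit of every test, as the design fixed before the data were examined allowed. The planned tests of gene lists, cell type markers, long non-coding RNA classes and a panel of named genes need gene names or classes and were not run. Transcripts of one locus overlap, and FPKM values of overlapping transcripts share fragments that the quantification has to divide, so the value of a single transcript is less certain than that of a gene. An exact 0 in such a table can be a failed estimate, and a transcript is therefore only said to be listed at 0.

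Transcripts with at least 0.5 FPKM in at least 2 of the 6 libraries were tested, which left 23407 transcripts, 23116 annotated and 291 unannotated. Values were taken to log2(FPKM + 0.5), and all fold changes are on that scale, which understates the change of low transcripts. Group means were compared with limma 3.58.1 in R 4.3.3 in 1 fit over the 6 libraries, with empirical Bayes moderation that follows an intensity trend, and p-values were adjusted by the Benjamini-Hochberg method within each comparison. A transcript is said to rise or fall where its adjusted p was under 0.05. The fit has 3 residual degrees of freedom per transcript and 1.68 prior degrees of freedom. The labels do not say whether the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. No batch or date is labelled.

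The test was checked on simulated libraries with the means and spreads of the 23407 transcripts and 200 changed ones. For triptolide against control it recovered 0.50% of changes of 1 log2 unit, 53.0% of changes of 2 and 83.0% of changes of 3. False calls were 0, 6 and 15 among 1, 112 and 181 calls. For triptonide against control the recovered shares were 1.0%, 67.0% and 88.0%, with 0, 15 and 11 false calls. Chance agreement between comparisons that share the control libraries was taken from 20 simulations of unchanged groups. The control libraries were simulated too, so the deviations of the real control libraries did not enter. The set of unannotated transcripts was tested with camera of limma, with the preset correlation of 0.01 and with an estimated one, and with fry. This set was chosen after the data were seen.

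Absolute depth is unknown. Among low FPKM values between 0.01 and 0.2, ratios between libraries piled up at steps that whole fragments would give, and 9 of the 15 pairs of libraries with a clear step set the relative depths. With a tolerance of 0.01 log2 units, 12 of the 15 pairs lay at the fitted ratio. On that scale the control libraries were the deepest at 0.818 and 1.0, the triptonide libraries had 0.764 and 0.737, and the triptolide libraries 0.598 and 0.673, a 1.67-fold range.

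The other settings tried were pseudocounts of 0.1 and 1, no filter or a minimum of 1 FPKM, 3 other scalings, fits of only the 2 groups compared, no intensity trend, the replicate number as a block, and each library left out in turn. The scalings were median-of-ratios factors, quantile normalization, and division by the summed FPKM outside the 100 most abundant transcripts. The naming rule fixed in advance takes transcripts with an adjusted p under 0.05, a mean of at least 1 FPKM and groups that do not overlap, ranked by fitted fold change. For triptolide against control 6216 transcripts met it. Because IDs are paired with no gene, only the 2 highest and 2 lowest of that ranking are named.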

Results

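Transcript levels were measured by RNA sequencing in GC2 cells exposed to triptolide or triptonide and in control cells, with 2 libraries per group. Triptolide is a diterpenoid of the vine Tripterygium wilfordii and a known inhibitor of transcription that binds the XPB subunit of the general transcription factor TFIIH. Triptonide is a close analog in which a ketone takes the place of a hydroxyl group of triptolide. The series asks how both compounds change the RNA of this germ line-derived cell line, with long non-coding RNA in its title. The table does not class transcripts, so the counts cover coding and non-coding transcripts together.

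Between 36592 and 41680 transcripts were listed above 0 FPKM per library. The control libraries had 36592 and 37997, fewer than the 41088 and 41680 after triptolide and the 40956 and 41054 after triptonide, although the control libraries were the deepest. Libraries of a group correlated across the tested transcripts with a Pearson r of 0.932 for control, 0.923 for triptolide and 0.924 for triptonide, against 0.820 to 0.900 between groups. These correlations are across transcripts, which are not independent replicates. In a principal component analysis the first component held 48.2% of the variance, and both triptonide libraries lay between the control and the triptolide libraries on it. The second component held 16.4% and set the triptonide libraries, at -47.7 and -52.7, apart from the other groups. Control lay there at 32.1 and 14.6 and triptolide at 27.1 and 26.6. The 10 most abundant transcripts were taken by mean FPKM over all 6 libraries, which favours transcripts that are high after treatment. They held 42.0% and 38.0% of the summed FPKM in control, 61.4% and 55.8% after triptolide, and 45.7% and 43.3% after triptonide. The transcript at rank 6 of the 10 had 9448 FPKM in triptonide replicate 1 and 0.075 FPKM in triptonide replicate 2, which lowered the share of the latter.

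Triptolide changed 8294 of 23407 tested transcripts, of which 2894 rose and 5400 fell. Changes of at least 2-fold were seen in 1668 transcripts that rose and 2657 that fell. The highest-ranked rise was that of ENSMUST00000200289, from 0.0898 ± 0.00053 FPKM in control to 97.9 ± 34.1 FPKM after triptolide (SD, n = 2), a log2 fold change of 7.34 ± 0.26 (SE; limma adjusted p = 0.000718). ENSMUST00000218604 followed with a rise from 0.0508 ± 0.020 to 82.1 ± 0.60 FPKM (SD, n = 2), a log2 fold change of 7.23 ± 0.14 (SE; limma adjusted p = 0.000505). The order of these rises turned with a pseudocount of 0.1, with 9.10 for ENSMUST00000218604 and 8.97 for ENSMUST00000200289. It also turned without triptolide replicate 2, with 7.22 and 6.98. The 2 transcripts at the other end of the ranking were listed at 0 in both triptolide libraries. ENSMUST00000191104 had 40.3 and 41.6 FPKM in the control libraries (limma adjusted p = 0.000505), and ENSMUST00000116669 had 37.2 and 38.6 FPKM (limma adjusted p = 0.000294). An exact 0 can be a failed estimate, and 2 equal values of 0 add no spread to the fit. The p-values of these 2 transcripts, in this and the other comparisons, may therefore be too small and their intervals too narrow.

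**Figure D1:**
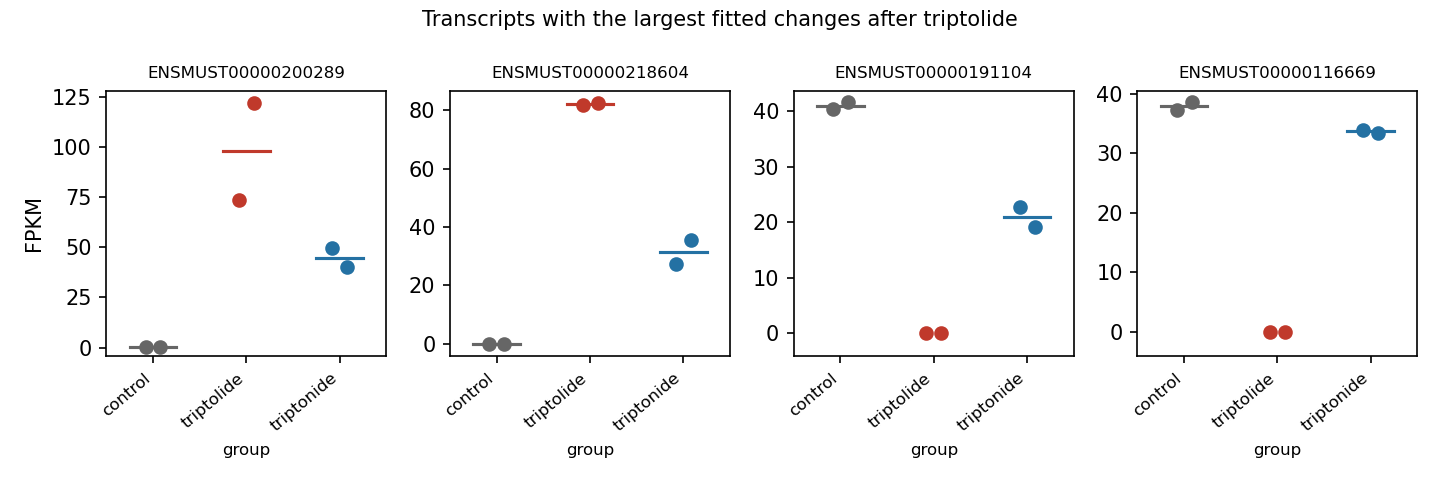
FPKM of the 4 named transcripts in each library on a linear axis, with points for single libraries (2 per group) and lines for group means, drawn only where no library is listed at 0. ENSMUST00000200289 and ENSMUST00000218604 were under 0.1 FPKM in control and at 73.8 FPKM or more after triptolide, while ENSMUST00000191104 and ENSMUST00000116669 were listed at 0 after triptolide and between 19.1 and 33.9 FPKM after triptonide.

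The balance of rises and falls after triptolide depended on the scaling. The median log2 fold change of all tested transcripts was -0.26 with FPKM as deposited and 0.01 with median-of-ratios scaling. Falls made up 65.1% of the calls as deposited, 54.2% after scaling to the sum outside the 100 most abundant transcripts, 49.1% after quantile normalization and 43.3% with median-of-ratios scaling, where 4217 transcripts rose and 3219 fell. Changes of at least 2-fold then numbered 2421 rises and 1369 falls. With a control library left out, the median log2 fold change as deposited was -0.27 without control replicate 1 and -0.23 without control replicate 2. In the design of 2 libraries against 2, both libraries of one group lay above both of the other for 70.2% of the transcripts, against 33.3% by chance. This share was taken on FPKM as deposited. A shift of whole libraries also separates groups, so the 33.3% holds only without such a shift.

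Abundant transcripts were called most often. In the most abundant quintile 41.9% of transcripts fell and 17.6% rose after triptolide, against 12.1% and 15.7% in the least abundant quintile. The median log2 fold change from the least to the most abundant quintile was -0.08, -0.21, -0.30, -0.38 and -0.29. The share of falls rose with each quintile, while the median moved further down only up to the quintile below the most abundant one. This median covers rises, falls and transcripts not called, and the log2 scale understates the change of low transcripts. In the least abundant quintile, falls were 4.49% without control replicate 1, 3.93% without control replicate 2, 4.53% without triptolide replicate 1 and 4.66% without triptolide replicate 2, and rises were 7.90% and 8.29% without control replicate 1 or 2. With median-of-ratios scaling the most abundant quintile had 25.4% falls and 30.8% rises, so the balance within it flipped with the scaling, while the share of falls still exceeded the 7.95% of the least abundant quintile. The 10 most abundant transcripts were chosen by mean FPKM over all 6 libraries, so high triptolide values helped a transcript into the set. All 10 had higher FPKM after triptolide, with a median log2 fold change of 1.18, and 9 of them rose. Under median-of-ratios scaling 9 rose as well. Quantile normalization, which forces the top values of all libraries to be equal, left the median log2 fold change of the 10 without a shift, with 1 rise and 2 falls.

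**Figure D2:**
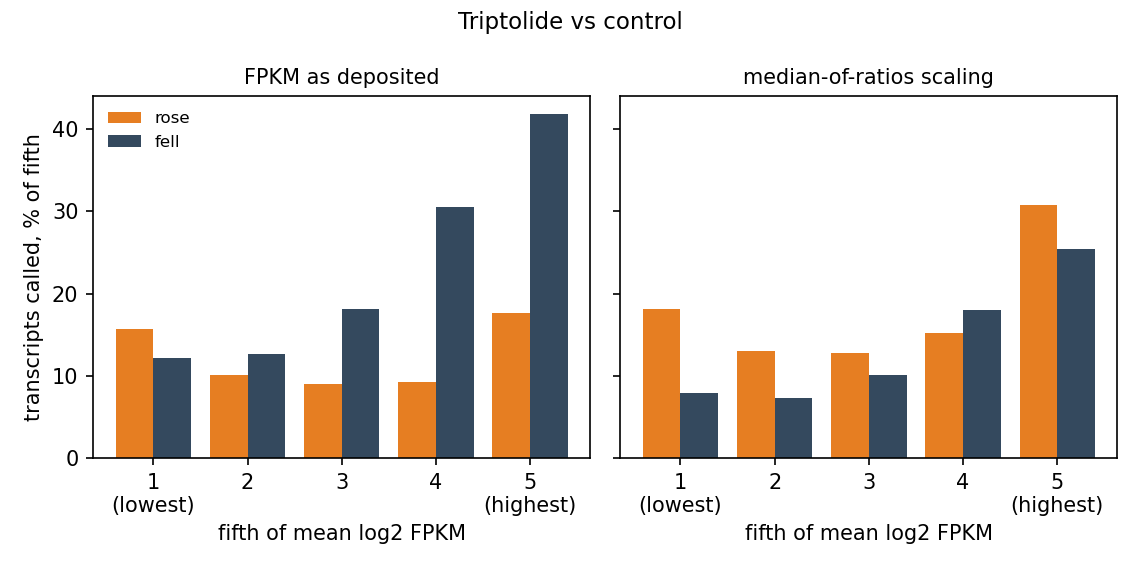
Share of transcripts that rose or fell after triptolide in each quintile of mean log2 expression, in percent of the quintile, with FPKM as deposited (left) and with median-of-ratios scaling (right). Falls reached 41.9% of the most abundant quintile as deposited and 25.4% with the other scaling, where rises reached 30.8%.

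Unannotated transcripts went up as a group after triptolide. Of the 291 tested, 156 rose and 26 fell, and their median log2 fold change was 1.48, against -0.26 for annotated transcripts. That median was 2.56 with a pseudocount of 0.1 and 1.02 with a pseudocount of 1. Their median over all 346 was 0.0494 and 0.0634 FPKM in the control libraries, 1.65 and 1.61 FPKM after triptolide, and 1.01 and 1.19 FPKM after triptonide. Per library, 191 and 196 of them were listed above 0 in control, 297 and 305 after triptolide, and 295 and 301 after triptonide. The set stood above the other transcripts by camera of limma (adjusted p = 7.46e-22 over the 3 comparisons, and adjusted p = 0.00895 with an estimated correlation). It was chosen after the data were seen, and assembly from mostly treated libraries may favour transcripts that are high after treatment. These p-values, and those of camera for the other comparisons, are therefore no separate evidence. The 291 transcripts come from 221 loci, of which 128 held a transcript that rose. Without control replicate 1 or control replicate 2, 106 and 110 rose and 10 fell in each case, and the medians were 1.53 in both.

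Some transcripts were listed at 0 throughout one group and at 1 FPKM or more throughout another. After triptolide, 191 transcripts had at least 1 FPKM in both libraries and were listed at 0 in both control libraries, and 71 of these were unannotated. The opposite pattern, at least 1 FPKM in both control libraries and 0 in both triptolide libraries, was seen for 73 transcripts. Of the 191, 73 also had at least 1 FPKM in both triptonide libraries.

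**Figure D3:**
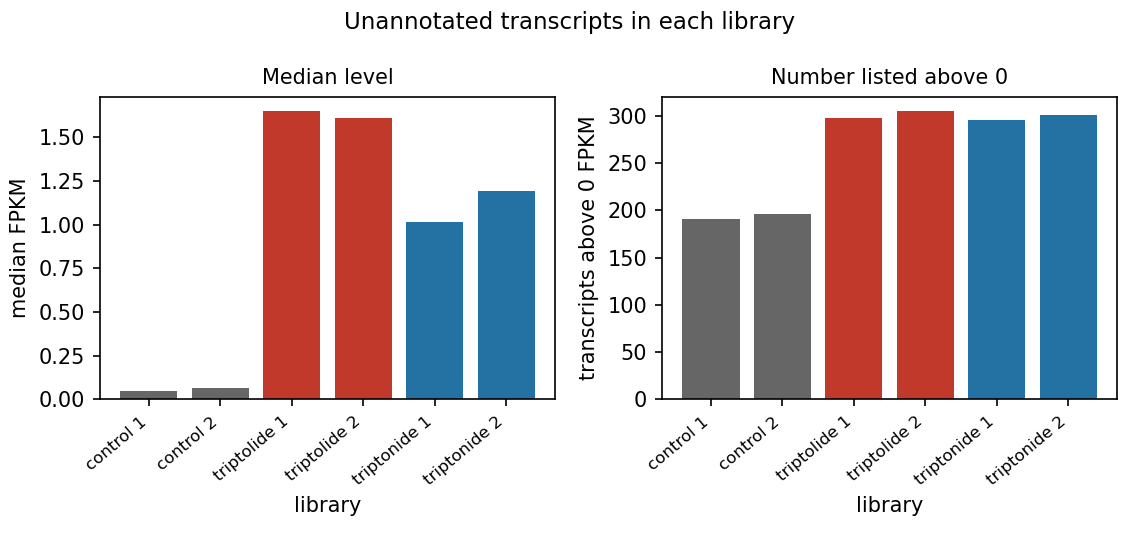
Median FPKM of the 346 unannotated transcripts in each library (left) and the number of them listed above 0 FPKM (right), with 1 bar per library. Both control libraries lay below every treated library in both plots, with 191 and 196 transcripts listed against 295 to 305.

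Triptonide changed 2488 transcripts against control, of which 1468 rose and 1020 fell. Changes of at least 2-fold were seen in 835 transcripts that rose and 240 that fell, and in 171 to 673 and 52 to 186 when any 1 library was left out. ENSMUST00000200289 rose to 44.8 ± 6.8 FPKM (SD, n = 2), a log2 fold change of 6.25 ± 0.26 (SE; limma adjusted p = 0.00276), and ENSMUST00000218604 to 31.4 ± 6.0 FPKM (SD, n = 2), a log2 fold change of 5.84 ± 0.14 (SE; limma adjusted p = 0.00128). ENSMUST00000191104 fell to 20.9 ± 2.6 FPKM (SD, n = 2), a log2 fold change of -0.96 ± 0.11 (SE; limma adjusted p = 0.0167). This call was lost without control replicate 1 (adjusted p = 0.102), control replicate 2 (adjusted p = 0.103) or triptonide replicate 2 (adjusted p = 0.0720). ENSMUST00000116669 did not pass the test after triptonide, at 33.7 ± 0.35 FPKM (SD, n = 2) and a log2 fold change of -0.17 with a 95% confidence interval of -0.36 to 0.03 (limma adjusted p = 0.238).

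Unannotated transcripts were also higher after triptonide, with 87 rises among 291 and a median log2 fold change of 0.80, against -0.01 for annotated transcripts. That median was 1.61 with a pseudocount of 0.1 and 0.53 with a pseudocount of 1. By camera of limma the set, chosen after the data were seen, had an adjusted p = 3.98e-16, and adjusted p = 0.00895 with an estimated correlation. In total 113 transcripts had at least 1 FPKM in both triptonide libraries and 0 in both control libraries, 27 of them unannotated, and 16 showed the opposite pattern. The number of calls fell with each library left out. That number also falls because a residual degree of freedom is lost, so it need not single out a library. It was 242 without control replicate 1, 291 without control replicate 2, 546 without triptonide replicate 1 and 322 without triptonide replicate 2. It was 1453 and 1466 without triptolide replicate 1 or 2, which enter only through the spread, and rises among unannotated transcripts were 12, 15, 26 and 18 without either control or either triptonide library, while their median stayed between 0.71 and 0.86.

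The direct comparison of the compounds asked where a ketone in place of the hydroxyl group went with another response, at a dose of triptonide that the labels do not give. In all, 3669 transcripts differed, of which 2821 were higher and 848 lower after triptonide. The effect had the same sign against control and was larger after triptolide in 2650 of the 3669, or 72.2%. This share was 70.0% to 74.4% under the 3 other scalings. Another 125 had the same sign and a larger effect after triptonide, and 894 had effects of opposite sign. With any 1 library left out these numbered 12 to 85 and 24 to 449, and the share with a larger effect after triptolide was 60.4% to 75.2%, lowest without triptonide replicate 1. ENSMUST00000116669, listed at 0 in both triptolide libraries, had 33.9 and 33.4 FPKM in the triptonide libraries (limma adjusted p = 0.000333). ENSMUST00000191104, also listed at 0, had 22.7 and 19.1 FPKM (limma adjusted p = 0.00130). The values of 0 add no spread to the fit, so these p-values may be too small. ENSMUST00000218604 was lower after triptonide by a log2 fold change of -1.39 with a 95% confidence interval of -1.76 to -1.01 (limma adjusted p = 0.00970), a call lost without triptolide replicate 1 (adjusted p = 0.0556), triptolide replicate 2 (adjusted p = 0.0505) or triptonide replicate 1 (adjusted p = 0.0507). For ENSMUST00000200289 the difference of -1.08 did not pass, with a 95% confidence interval of -1.78 to -0.39 (limma adjusted p = 0.0595). It passed with median-of-ratios scaling (adjusted p = 0.0331), with scaling to the sum outside the 100 most abundant transcripts (adjusted p = 0.0475) and without triptolide replicate 1 (adjusted p = 0.0445).

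Unannotated transcripts were lower after triptonide than after triptolide, with a median log2 fold change of -0.50 against 0.24 for annotated transcripts, 51 falls and 10 rises. Camera of limma on this set, chosen after the data were seen, gave an adjusted p = 1.00e-17, and adjusted p = 0.00895 with an estimated correlation. With median-of-ratios scaling the unannotated set had a median of -0.77, with 79 falls and 5 rises. With quantile normalization these were -0.75, 70 and 7, and after scaling to the sum outside the 100 most abundant transcripts -0.60, 58 and 7. The direction over all transcripts depended on the scaling, since the median log2 fold change of 0.24 moved to -0.0035 with median-of-ratios scaling. Transcripts lower after triptonide made up 23.1% of the calls as deposited, 35.3% after scaling to the sum outside the 100 most abundant transcripts, 49.0% after quantile normalization and 61.0% with median-of-ratios scaling, where 1123 were higher and 1755 lower. The number of calls fell to 91 without triptonide replicate 1 and to 1261 without triptonide replicate 2. It was 1155 without triptolide replicate 1, 1646 without triptolide replicate 2, and 1937 and 1940 without control replicate 1 or 2. Without each of these libraries, in the same order, the falls among unannotated transcripts numbered 1, 21, 16, 20, 23 and 23, with medians from -0.55 to -0.40.

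For many transcripts a difference between the compounds was not resolved. The 95% confidence interval of the difference lay within 1 log2 unit of 0 for 11061 transcripts, or 47.3%. For 10193 transcripts that were not called, the interval reached beyond 1 log2 unit, so a 2-fold difference is not excluded. Over all tested transcripts the median width of the interval to either side was 0.57.

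The effects of both compounds against control went together. Their Pearson correlation across transcripts was 0.744 and Spearman's rho was 0.732. Simulated unchanged groups that shared 2 simulated control libraries gave 0.498 and 0.454. The covariance of 0.512 exceeded the simulated 0.0827 by 0.429. The slope of triptonide on triptolide effects after this subtraction was 0.561. In total 1238 transcripts rose and 941 fell after both compounds, where independent lists of these lengths would share 182 and 235. The simulated unchanged groups shared 0 and 0, but with on average 0.05 calls for triptolide and 0 for triptonide they could share none, so this says nothing about the overlap that shared controls can add. Part of the excess may come from the shared controls, which cannot be split into parts of 2 libraries. The shared rises and falls numbered 164 and 52 without control replicate 1, 194 and 68 without control replicate 2, 740 and 487 without triptolide replicate 1, 753 and 494 without triptolide replicate 2, 306 and 179 without triptonide replicate 1, and 186 and 95 without triptonide replicate 2.

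Among the 2894 transcripts that rose after triptolide, 95.5% had a fold change above 0 after triptonide, with a median log2 fold change of 1.10 for triptolide and 0.69 for triptonide. In simulated unchanged groups that shared simulated controls, as many transcripts chosen by the smallest triptolide p had the same sign in 80.5%. Among the 5400 that fell, 90% were below 0 after triptonide, with medians of -0.99 and -0.36, where the simulation gave 76.2%. Over all transcripts 76.7% had the same sign, against 66.7% in the simulation. These sets were chosen on the triptolide values, which favours the larger size there, and both sides share the control libraries. For the 1468 chosen on a rise after triptonide the medians were 1.20 for triptolide and 1.09 for triptonide, and for the 1020 that fell after triptonide they were -1.28 and -0.71.

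**Figure D4:**
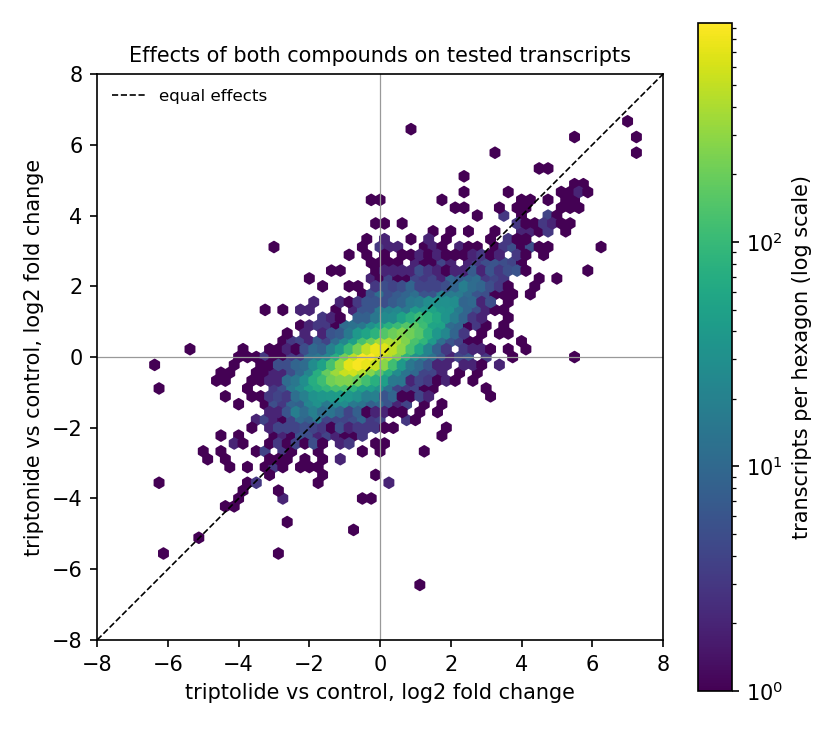
Log2 fold change against control of each tested transcript after triptolide (horizontal) and triptonide (vertical), as a density of 23407 transcripts with the number per hexagon on a log colour scale. The dashed line marks equal effects. The Pearson correlation was 0.744, and simulated unchanged groups that shared simulated control libraries gave 0.498.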

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

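The limma test between the compounds was planned, the test on matched annotated transcripts was set before its outcome was known, and the other tests of the unannotated transcripts and the count of opposite calls were chosen after the result was seen. Effects that differed between the compounds were taken up here because the difference itself passed a test. A total of 3669 transcripts differed between triptonide and triptolide by limma. Against control, 14 transcripts were called in opposite directions by the compounds. For such transcripts the difference between the compounds is the sum of both effects, so their calls between the compounds follow from those against control and are no separate evidence. The number of opposite calls was 14 under each of the 3 other scalings. It was 3 without a filter, 6 with only the 2 groups compared in the fit, 8 without an intensity trend and 1 with the replicate number as a block. It was also lower than 14 with any 1 library left out.

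Unannotated transcripts were higher after both compounds and lay lower after triptonide than after triptolide, with a median log2 fold change of -0.50 between them. One technical candidate explanation is that transcripts enter the assembly because a library expressed them, and 4 of the 6 libraries were treated. In 1000 sets of annotated transcripts matched on their highest group mean, the median triptolide log2 fold change lay between -0.51 and -0.13. The unannotated transcripts had 1.48. Annotated transcripts did not have to be assembled from these libraries to be listed, so the match does not mimic that entry. The test therefore does not decide, and this explanation stays open. Library depth is argued against, since the control libraries were the deepest. The highest control library listed 99 fewer unannotated transcripts above 0 than the lowest treated library (a difference of -99). A response of the cells to the compounds stays open, as does a source of reads that the table cannot show, because it gives no coordinates or sequences for these loci.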

How the results depend on the processing

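The alternatives were planned before the data were examined, except the fold minimum, the removal of transcripts that swing within a group, and every alternative for the unannotated transcripts. Calls for triptolide against control stayed within 1.5-fold of 8294 under the other pseudocounts, filters, scalings and fits, and with a fold of at least 2 they numbered 4325. Calls for triptonide against control moved from 2488 to 1273 without a filter, where 50307 transcripts were tested, to 1552 with only the 2 groups in the fit, and to 1075 with a fold of at least 2. Calls between the compounds moved from 3669 to 1820 with only the 2 groups in the fit, which leaves fewer samples to estimate the spread, and to 1081 with a fold of at least 2. Leaving out 1 library gave 4787 to 7412, 242 to 1466 and 91 to 1940 calls in these comparisons. The lone library left in a group is then assumed to vary like the other groups. The correlation of effects of 0.744 moved to 0.712 without a filter and 0.713 with quantile normalization, for which the cause was not tested, and lay between 0.652 and 0.778 with 1 library left out. The correlation and the fold changes of the named transcripts did not change sign under any alternative run for them. Of the transcripts called as deposited, 3 were called in the opposite direction for triptolide with median-of-ratios scaling. With quantile normalization these were 3 for triptolide and 3 between the compounds. Many more calls were lost. Median-of-ratios scaling kept 73.7% of the triptolide, 88.4% of the triptonide and 53.7% of the between-compound calls in the same direction. Quantile normalization kept 75.3%, 76.1% and 55.1%, and scaling to the sum outside the 100 most abundant transcripts 85.2%, 90.7% and 78.9%. For the named transcripts 194 comparisons under alternatives kept their side of the threshold, 7 lost the call and 3 gained it. The medians of the unannotated transcripts kept their sign in all 54 cases, but their size followed the pseudocount, from 1.02 to 2.56 for triptolide and from 0.53 to 1.61 for triptonide.

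With the replicate number as a replicate block, 6765, 598 and 1639 transcripts were called for triptolide, triptonide and between the compounds, and the triptonide call of ENSMUST00000191104 was lost (adjusted p = 0.0567). The numbers do not pair the samples, since the deviations of same-numbered libraries correlated at only -0.037, 0.0096 and 0.014. Alternatives on long non-coding RNA classes, gene lists, markers and named genes were not run, because transcripts were not tied to genes. With 200 changed transcripts in simulation, changes of 1 log2 unit were recovered in at most 1.0% of cases, but the adjustment is laxer where many transcripts change, as after triptolide.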

Other observations

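The scaling to the sum outside the 100 most abundant transcripts was planned, but its use as a test of an explanation and the test by abundance were chosen after the result was seen, and the test on neighbouring transcripts was set before its outcome was known. More transcripts fell than rose after triptolide with FPKM as deposited. A candidate explanation is that a few abundant transcripts took more of the total in the triptolide libraries and so lowered every other FPKM. With FPKM scaled to the sum outside the 100 most abundant transcripts, falls made up 54.2% of the calls. That scaling shifts all transcripts of a library alike and left their median log2 fold change at -0.12, so it does not decide whether this was the source, which stays open. Shallower triptolide libraries would mainly take away rare transcripts, but the share of falls in the most abundant quintile was 29.7 percentage points above that in the least abundant. The log2 scale understates changes of low transcripts, and falls after triptonide had the same order, with 13.2% against 1.75%. The share of calls therefore does not decide whether depth played a part. FPKM is relative to the library total, so a loss of most RNA alike in treated cells, which an inhibitor of transcription may cause, was not tested and stays open.

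Single transcripts differed from 10 FPKM or more to under 0.1 FPKM between the 2 libraries of a group in 46 cases in control, 37 after triptolide and 47 after triptonide, 116 transcripts in all. If reads had moved between overlapping transcripts of one locus, a transcript nearby in the table should show the opposite change. Of these 130 swings, 53.8% had an opposite change of similar size, within a factor of 2, at most 5 rows away, against 1.54% to 16.2% in 1000 random sets of rows of the same abundance. The reassignment of reads between isoforms may thus lie behind many of them, and a transcript listed at 0 in both libraries of a group could arise in the same way. Not all of the 116 transcripts had passed the filter for testing. Without them, an alternative added after the data were seen, 23317 transcripts were tested. Of these, 8368, 2536 and 3711 were called in the 3 comparisons.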
